A study of Homo sapiens with 78 samples.

How the data were processed

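Gene expression was measured in needle biopsies of human kidney transplants with Illumina bead arrays, on which each probe is a short DNA sequence carried by beads. Per the labels' protocols, specimens were frozen in a stabilising solution, total RNA was isolated with TRIzol and a column clean-up, and biotin-labelled cRNA was prepared with a commercial amplification kit before hybridisation. The labels place 78 arrays in 6 groups by the result of the crossmatch, the day of the protocol biopsy and the use of eculizumab, an antibody that blocks complement component C5. A positive crossmatch means that the recipient's serum held antibodies that bound cells of the donor. The groups are 10-day positive crossmatch biopsies without the drug (15 arrays) and on it (18), 90-day positive crossmatch biopsies without the drug (14), still on it (9) and after it was stopped (9), and 90-day negative crossmatch biopsies (13), which are the controls. The labels do not tie biopsies to separate patients, so p-values measure the spread between these biopsies. The biopsy numbers in the labels were not taken to pair biopsies across groups. They run from 1 to 18 at 10 days on the drug, 1 to 9 at 90 days on it and 10 to 18 after it was stopped. The same patients may therefore lie behind both days, which the labels do not state, and the tests treat all biopsies as independent.

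The values are log2 signals, as deposited by the authors in 1 table of 47323 probes. That they are on a log2 scale was read from the values, which run from 4.48 to 15.9 with array medians between 6.42 and 6.45. The near-equal medians point to a normalisation between arrays before deposit. Its method, the background correction and the software are not given in the sources used here. The signals were used as deposited, with no further normalisation, offset or background step. The number of arrays limits the precision of each value.

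Probes were named from the platform annotation given with the data. Of the probes, 30113 carry 1 gene symbol, 8 carry several and 17201 carry none there; those with several or none were left unnamed and untested. A RefSeq gene table matched 30074 of the 1-symbol probes and was used for names only, and 0 symbols were updated. The 1 probe without a value on every array was left out. The 144 probes of Y chromosome genes, XIST and TSIX were left out because they carry a person's sex. Where a gene had several probes (6659 genes), the probe with the highest mean over all arrays stood for it, which left 19951 genes. No gene was dropped for a low signal, so differences of genes near the background understate a change.

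All arrays entered 1 linear model with a mean for each group, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean level). Differences between group means were tested for 11 pairs of groups, and a further contrast set the drug's difference at 10 days against that at 90 days. Benjamini-Hochberg adjustment ran over all genes tested in a comparison, and genes with an adjusted p under 0.05 were called. Standard errors are those of the fit, and SDs are those of the biopsies of a group.

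The 24 gene lists, with 588 entries of which 552 were measured, were written before the data were examined. They cover IFNG-inducible genes, type I interferon-stimulated genes, HLA class I and class II antigen presentation, T cell, B cell, plasma cell, macrophage and monocyte and neutrophil markers, NK and cytotoxic genes, endothelial genes, complement genes, tubular injury and repair genes, markers of the proximal tubule, of the loop, distal tubule and collecting duct, and of podocytes, erythrocyte genes, extracellular matrix and fibroblast genes, proliferation genes, immediate early and stress genes, glucocorticoid-responsive and metallothionein genes, hypoxia-responsive genes, oxidative phosphorylation genes and cytosolic ribosomal protein genes. A few genes stand in more than 1 list. Each list was tested with camera, from limma, with its preset correlation of 0.01 between genes, and adjusted over the 24 lists. Camera with a correlation estimated from the arrays was run as well. A two-sided permutation test of each list's mean, with 1 value per biopsy, was added after the data were seen, because lists of co-regulated genes were called too readily at the preset correlation. It was exact where a group had fewer than 10 biopsies and used 100000 draws otherwise, and it was adjusted over the 24 lists. Members were also counted with p-values adjusted over the list alone.

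The fit was tested on simulated data with 200 changed genes among 19951. For 90-day biopsies without the drug against controls, it recovered 93% of genes changed 1.5-fold and 97.6% of those changed 2-fold. The changed genes were picked at random from all genes, whose median SE in this comparison was 0.0623. These rates do not carry over to genes that vary more between biopsies, so an uncalled gene may still have changed by more. Over the 11 pairs of groups, the median number of unchanged genes called ran from 3.5 to 8.5, and the highest in a single simulation was 698, for 90-day biopsies on the drug against controls. With no change between the groups, the preset correlation called a median of 5.5 to 12.5 lists, by comparison, and the estimated correlation a median of 0.

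Genes are named by a rule written before the data were examined: called genes with the largest differences in each direction (10 and 10 for 4 main comparisons, 5 and 5 for the others), the 3 members with the smallest p of each list that camera called or that had at least 3 called members, the 3 genes with the smallest p where no gene was called, and a fixed set that includes the drug's target C5 and markers such as CXCL9, CD3D and VWF.

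Arrays were compared with each other first. The highest correlation between 2 arrays was 0.9914, and no array was a copy of another. The median correlation of an array with the others was 0.9818 in the middle of the arrays. It was under 0.965 for 7 arrays, namely biopsy 1 of the 10-day group without the drug, biopsies 4, 8, 13 and 16 of the 10-day group on it, biopsy 14 of the 90-day group without it and control biopsy 5. These stayed in the fit. For 4 arrays the sorted values were the same within 0.002, and the other arrays differed slightly in their distribution.

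Other settings chosen before the data were seen were cyclic loess normalisation, only genes above the middle of mean level, only the arrays of the groups compared, array weights, the biopsy number as a block, every probe by itself and the estimated correlation in camera. A fit without the 7 arrays that stand apart, a fit with the mean of the proximal tubule list as a covariate and the permutation test of list means were added after seeing the data. So were list means without a single biopsy that stands apart, and the arrays of the block fits without the block. Permutations and tables were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.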

Results

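Expression of 19951 genes was compared across 78 kidney transplant biopsies in 6 groups. Protocol biopsies, which are taken on a set day whatever the state of the graft, came from positive crossmatch transplants at 10 and 90 days and from negative crossmatch controls at 90 days. No control group at 10 days was analysed here, so in comparisons of 10-day biopsies with controls the day and the crossmatch change together. For 10-day biopsies on the drug, the drug changes with them. In 90-day biopsies on the drug or after it was stopped, the drug and the crossmatch differ together from the controls. The number of genes called in each comparison ran from 0 to 1545.

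**Figure D1:**
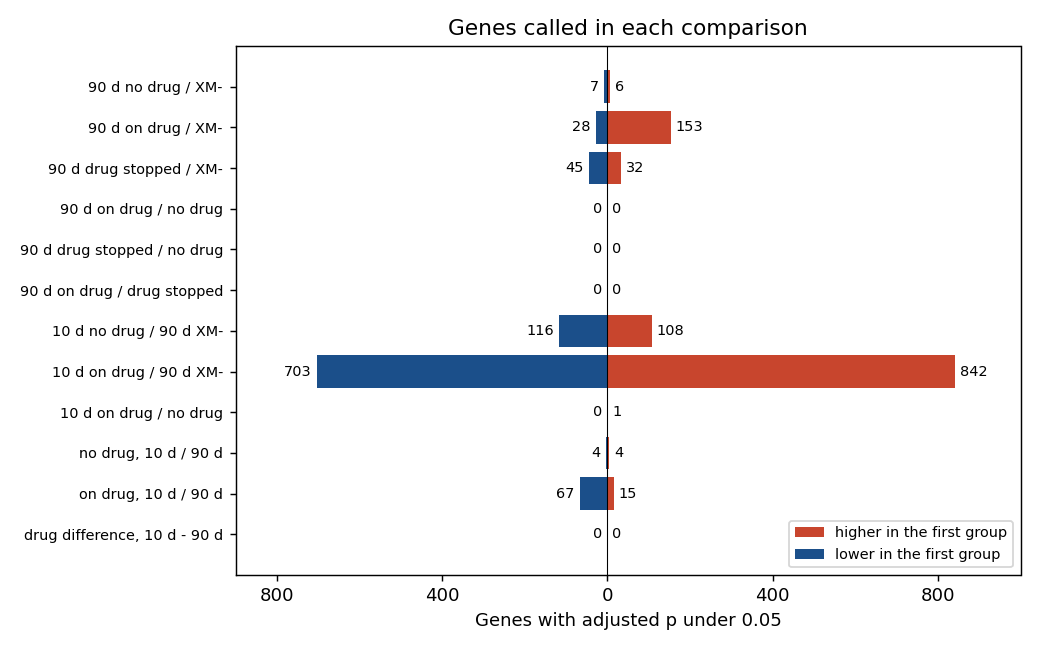
Number of genes with an adjusted p under 0.05 in each of 12 comparisons, with genes higher in the first group to the right and lower genes to the left. The largest count, 842 higher and 703 lower, belongs to 10-day biopsies on eculizumab against the controls, and the 3 comparisons between 90-day positive crossmatch groups have 0.

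The first comparison set 90-day positive crossmatch biopsies without the drug (n = 14) against the 90-day controls (n = 13). Genes induced by interferon gamma (IFNG) were higher. CXCL10, a chemokine that draws T cells, differed by 1.54 ± 0.48 (log2, SE). IRF1, a transcription factor of the interferon response, differed by 0.85 ± 0.26 and PSMB8, a subunit of the immunoproteasome, by 0.68 ± 0.21. None of these passed alone (adjusted p = 0.216, 0.204 and 0.214), and they lay above the control mean in 12, 12 and 13 of 14 biopsies. As a list, 0 of the 19 IFNG-inducible genes were called over all genes and 15 were higher when adjusted over the list alone. The list mean differed by 0.59 (permutation adjusted p = 0.0289), with 12 of 14 biopsies above the control mean. Adjusted p = 0.109 with an estimated correlation. Class II antigen presentation genes (8 of 14 higher when adjusted over the list alone, 0 over all genes) and class I genes (7 of 14, and 0 over all genes) had median differences of 0.49 and 0.39. Each had a permutation adjusted p of 0.0289, and adjusted p = 0.107 with an estimated correlation. In both, 12 of 14 biopsies lay above the control mean.

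NK and cytotoxic genes, which include NKG7 (0.78 ± 0.21) and granulysin, GNLY, had 7 of 26 members higher when adjusted over the list alone. Macrophage and monocyte markers had 8 of 25, and 0 were called over all genes in either. Their list means differed by 0.28 and 0.43 in 10 and 12 of 14 biopsies (permutation adjusted p = 0.0424 for both). Adjusted p = 0.107 and 0.236 with an estimated correlation. Tubular injury and repair genes had 0 of 31 members past either adjustment and a list mean 0.26 higher in 12 of 14 biopsies (permutation adjusted p = 0.0424), and adjusted p = 0.361 with an estimated correlation. Erythrocyte genes had a list mean that differed by -0.42 in 13 of 14 biopsies (permutation adjusted p = 0.0289), and adjusted p = 0.107 with an estimated correlation. Of the 11 genes 0 were called over all genes and 4 were lower when adjusted over the list alone. The median member differed by only -0.075. Proximal tubule markers had a mean difference of -0.349 in 10 of 14 biopsies, which did not pass the permutation test.

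The 13 genes called in this comparison, 6 higher and 7 lower, belonged to no list and all changed by less than 1.5-fold. COPG2, a subunit of the coatomer of transport vesicles, rose by 0.46 ± 0.072 (adjusted p = 0.000172), PPP3R1, the regulatory subunit of calcineurin, by 0.46 ± 0.073 (adjusted p = 0.000172). TAF5L, part of a histone acetylating complex, rose by 0.24 ± 0.040 (adjusted p = 0.000365). Each was above the control mean in 14 of 14 biopsies. Among the genes that fell, YIPF3 of the Golgi differed by -0.35 ± 0.061 (adjusted p = 0.0012), and TEX261 by -0.34 ± 0.061 (adjusted p = 0.00188). PMPCA, a mitochondrial processing peptidase, differed by -0.31 ± 0.062 (adjusted p = 0.0104). Each was below the control mean in 14 of 14. HNRNPA3, PBX2 and MFHAS1 also rose and THOC5, GLOD4, TLDC2 and MRRF also fell, by 0.26 to 0.35 on the log2 scale. TAF5L has 1 other probe, and it did not share the direction. Array weights gave 763 genes and leaving out the 7 arrays that stand apart 136, both including all 13, whereas cyclic loess gave 8, every probe by itself 7 and the arrays of the 2 groups alone 11, of which 7 were among the 13. With the biopsy number as a block 1 gene was called and 0 of the 13 were kept, against 11 genes on the same arrays without the block.

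The second comparison set 90-day biopsies still on eculizumab (n = 9) against the controls. The chemokine genes CXCL9 and CXCL10 rose 5.70-fold (2.51 ± 0.56, adjusted p = 0.0162) and 5.42-fold (2.44 ± 0.54, adjusted p = 0.0156), above the control mean in 9 of 9 biopsies. UBD, which encodes a ubiquitin-like modifier, rose 2.98-fold and the interferon-induced GTPase GBP1 rose 2.78-fold. FCN1, a lectin of monocytes, rose 2.88-fold, whereas ESM1, a proteoglycan secreted by endothelium, differed by -0.75 ± 0.18 (adjusted p = 0.0221). In all, 181 genes were called, 153 higher and 28 lower, of which 93 and 1 changed by at least 1.5-fold.

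**Figure D2:**
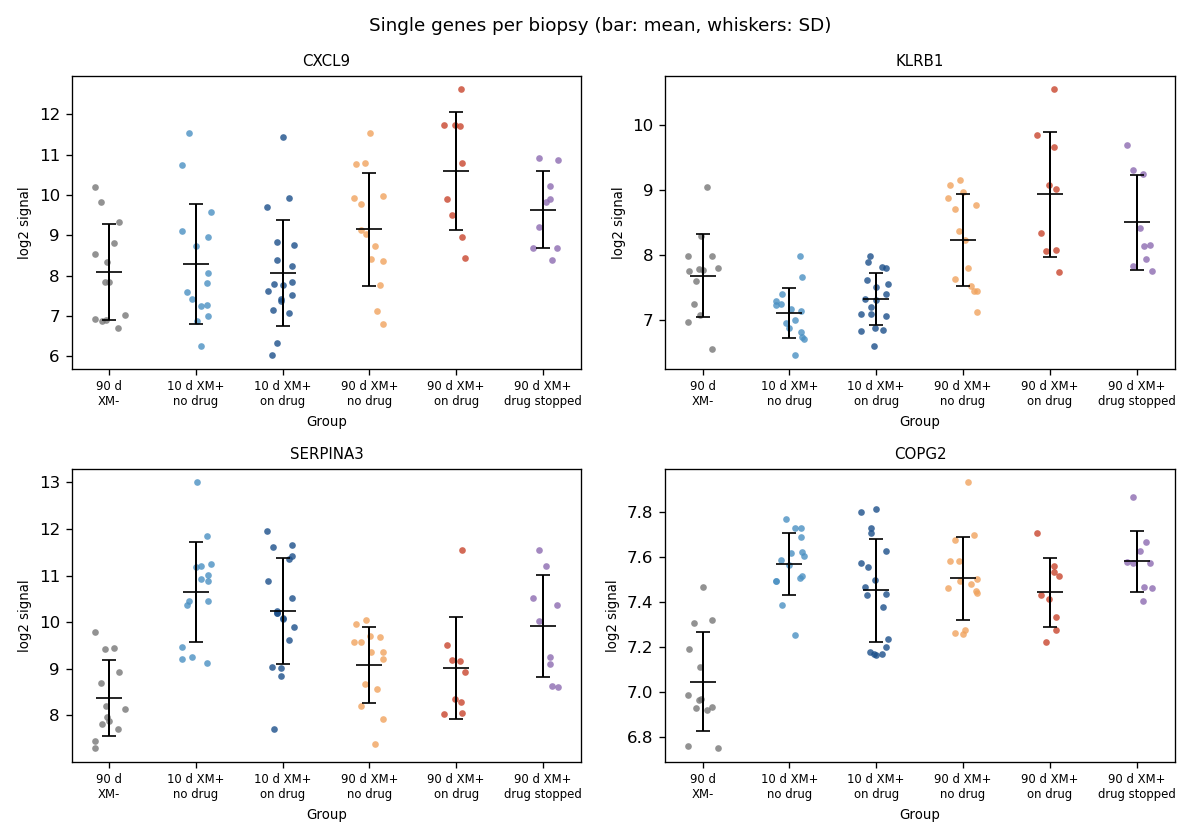
Log2 signal of CXCL9, KLRB1, SERPINA3 and COPG2 in each biopsy (points) of the 6 groups, with the group mean (bar) and SD (whiskers). CXCL9 has its highest mean, 10.6, in 90-day biopsies on the drug against 8.09 in controls, KLRB1 is lowest in both 10-day groups, SERPINA3 is highest in them, and COPG2 is lowest in the controls at 7.04.

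Of the 19 IFNG-inducible genes, 14 rose in these biopsies and 17 were higher when adjusted over the list alone (median 1.06, exact permutation adjusted p = 0.000917, 9 of 9 biopsies). The call held with an estimated correlation (adjusted p = 0.00584). NK and cytotoxic genes had 13 of 26 called over all genes and 18 adjusted over the list alone. Among them GNLY rose by 1.36 ± 0.25 (adjusted p = 0.00209). KLRD1, a receptor chain of NK cells, rose by 0.75 ± 0.14 (adjusted p = 0.00209) and NKG7 by 1.23 ± 0.24 (adjusted p = 0.0068), all in 9 of 9 biopsies. Of the T cell markers 4 of 21 were called over all genes and 12 when adjusted over the list alone. They included CD8A (0.90 ± 0.22) and CD247 (1.08 ± 0.23), the zeta chain of the T cell receptor. Macrophage and monocyte markers had 7 of 25 called (17 adjusted over the list alone), with CSF1R at 1.23 ± 0.27 and C1QC at 1.39 ± 0.32. Class II genes had 7 of 14 (11 adjusted over the list alone), with CD74, the invariant chain, at 1.22 ± 0.25. Class I genes had 6 of 14 (11 adjusted over the list alone), with HLA-E at 0.93 ± 0.20.

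Complement genes had 3 of 23 called over all genes and 10 adjusted over the list alone, including C3AR1, a receptor for a fragment of C3 (0.50 ± 0.12). Endothelial genes had 1 of 30, the endothelial membrane protein PLVAP (0.72 ± 0.18), and 10 adjusted over the list alone. With an estimated correlation the NK and cytotoxic (adjusted p = 0.00347), class II (0.00584), class I (0.0105), T cell (0.0181), macrophage (0.0316), complement (0.0329) and endothelial (0.0329) calls held. Their list means were 0.52, 0.79, 0.65, 0.33, 0.73, 0.37 and 0.33 higher, with 9 of 9 biopsies above the control mean in each. The type I interferon list (0 of 22 over all genes and 0 adjusted over the list alone) had a mean 0.29 higher in 7 of 9 biopsies. It passed the exact permutation test (adjusted p = 0.0457), but adjusted p = 0.388 with an estimated correlation. Transcript of C5, the drug's target, differed by -0.22 ± 0.14 (adjusted p = 0.69). With the biopsy number as a block 0 genes were called, against 125 on the same 18 arrays without the block. A shared number cannot mark the same transplant in these 2 groups, whose crossmatch differs. Array weights gave 668 genes, the arrays of these 2 groups alone 328, leaving out the 7 arrays that stand apart 485 and the proximal tubule covariate 302.

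The third comparison set 90-day biopsies after the drug was stopped (n = 9) against the controls, with 32 genes higher and 45 lower. CD74 rose 1.995-fold (0.996 ± 0.245, adjusted p = 0.0405, 8 of 9 biopsies). CTSZ, a lysosomal protease, rose by 0.88 ± 0.18 (adjusted p = 0.00782), APP, the amyloid precursor protein, by 0.80 ± 0.17 (adjusted p = 0.00782). MARCKS, an actin-binding kinase substrate, rose by 0.88 ± 0.22 (adjusted p = 0.0431), and each of these was higher in 9 of 9 biopsies. TM7SF2, a sterol reductase, differed by -0.67 ± 0.14 (adjusted p = 0.00782). The probes for the hormone genes AVP and OXT differed by -0.93 ± 0.20 and -0.79 ± 0.17 (adjusted p = 0.0122 and 0.0108), all in 9 of 9.

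No IFNG-inducible gene was called here over all genes and 15 of 19 were higher when adjusted over the list alone. The list mean was 0.74 higher in 9 of 9 biopsies (exact permutation adjusted p = 0.00599; adjusted p = 0.158 with an estimated correlation). Type I interferon-stimulated genes had 16 of 22 higher adjusted over the list alone and 0 over all genes, among them OAS2 (0.86 ± 0.28) and ISG15 (0.99 ± 0.33). The mean was 0.47 higher in 8 of 9 (exact permutation adjusted p = 0.011; adjusted p = 0.158 with an estimated correlation). Without biopsy 17, which stands apart in this list, it was 0.29 higher (exact permutation adjusted p = 0.0277), and ISG15 was 0.68 higher. Tubular injury and repair genes had 8 of 31 adjusted over the list alone, among them SERPINA3, an acute-phase protease inhibitor (1.55 ± 0.43), and 0 over all genes. The mean was 0.49 higher in 8 of 9 (exact permutation adjusted p = 0.00599; adjusted p = 0.158 with an estimated correlation). Class I, class II and NK and cytotoxic genes had means 0.54, 0.64 and 0.35 higher in 8, 8 and 9 of 9 biopsies (exact permutation adjusted p = 0.00599 each; adjusted p = 0.157 with an estimated correlation). They had 11, 9 and 12 members adjusted over the list alone and 0, 1 and 0 over all genes.

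Macrophage (mean 0.52 higher), complement (0.29), T cell (0.24) and endothelial (0.28) lists passed the exact permutation test too (adjusted p = 0.0131, 0.011, 0.0285 and 0.0285, in 8, 8, 9 and 9 of 9 biopsies). They had 0 members called over all genes and 7, 5, 9 and 1 adjusted over the list alone. Adjusted p = 0.222, 0.208, 0.158 and 0.158 with an estimated correlation. Oxidative phosphorylation genes were slightly lower, with a mean difference of -0.085 in 7 of 9 biopsies (exact permutation adjusted p = 0.0285; adjusted p = 0.502 with an estimated correlation). Of the 34, 1 was called over all genes and adjusted over the list alone, NDUFA10 of respiratory complex I (-0.43 ± 0.10). Proximal tubule markers had a mean difference of -0.52 in 8 of 9 biopsies that did not pass (exact permutation adjusted p = 0.143; adjusted p = 0.389 with an estimated correlation), with 0 of 27 called over all genes and 0 adjusted over the list alone. In the matrix list, COL15A1, a collagen of basement membranes, rose by 0.59 ± 0.15 (adjusted p = 0.0411), as 1 of 32 called, against 6 adjusted over the list alone. The count was 200 with only genes above the middle of mean level, 741 with the arrays of the 2 groups alone, 1849 with array weights, 1584 without the arrays that stand apart and 41 with the proximal tubule covariate. With the biopsy number as a block it was 0, as it was on the same 8 arrays without the block.

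**Figure D3:**
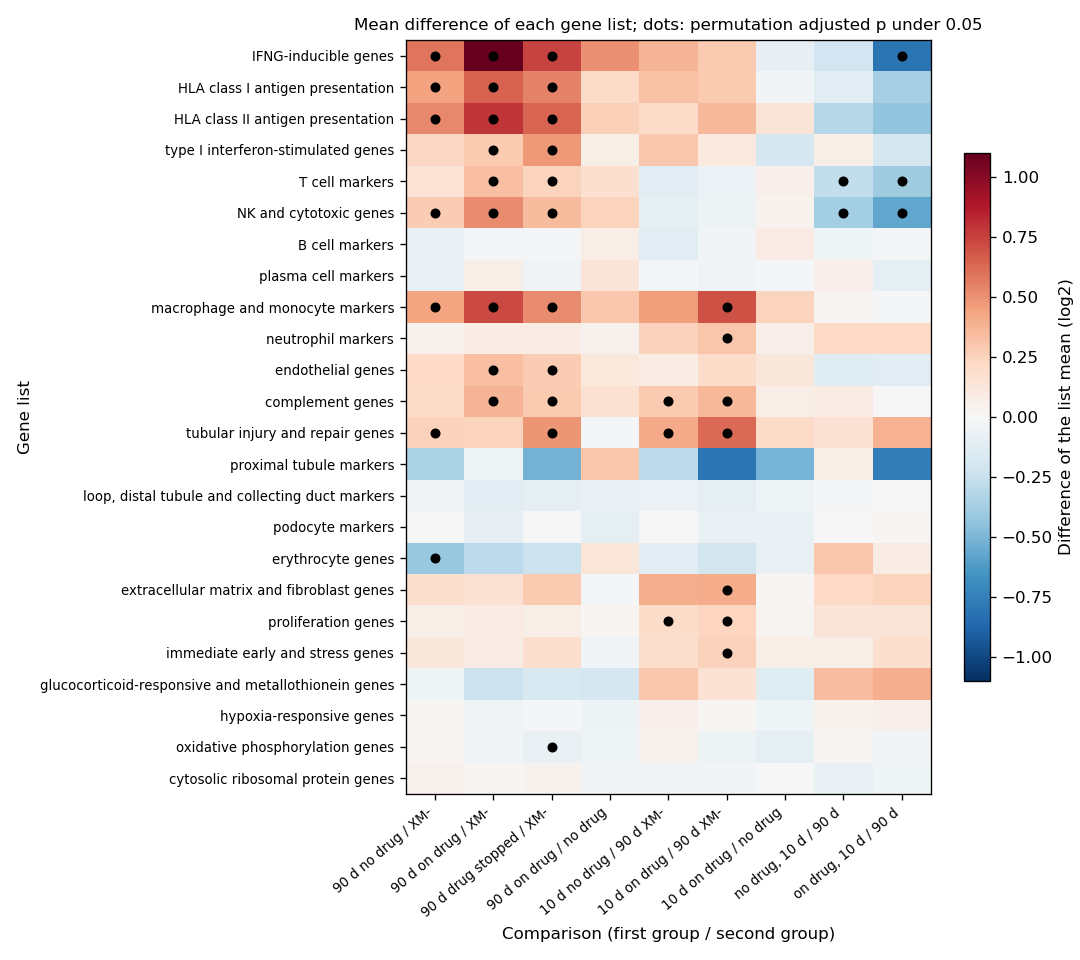
Difference in the mean of each of 24 gene lists (colour, log2, red higher in the first group) for 9 comparisons, with dots where the permutation test had an adjusted p under 0.05. The interferon, antigen presentation, T cell, NK and macrophage lists are red in the 3 columns of 90-day groups against controls, with the highest value, 1.09, for IFNG-inducible genes on the drug.

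The 3 positive crossmatch groups at 90 days were then compared with each other. Between biopsies on the drug and without it, limma called 0 genes, with 675 at an unadjusted p under 0.05. CXCL9 differed by 1.45 ± 0.55, KLRB1, a receptor of NK and T cells, by 0.71 ± 0.26 and GBP5 by 0.78 ± 0.29, none of which passed (adjusted p = 1 each; 7, 6 and 6 of 9 biopsies). The genes with the smallest p were FAM89A (-0.45 ± 0.11), MRGPRX3 (0.12 ± 0.028) and PHOX2A (-0.14 ± 0.034), each with adjusted p = 0.755 and each in 9 of 9 biopsies. They were picked by p in these same arrays, so that count lends no further support. Camera called 14 lists at its preset correlation, among them IFNG-inducible genes (median 0.46, 0 of 19 called over all genes and 0 adjusted over the list alone). Others were NK and cytotoxic genes (0.17, 0 of 26 by both) and plasma cell markers (0.12, 0 of 13 by both). Adjusted p = 0.166, 0.111 and 0.111 with an estimated correlation, and the exact permutation test called 0 lists.

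Between biopsies after the drug was stopped and without it, limma called 0 genes, with 620 at an unadjusted p under 0.05. The smallest p-values belonged to KRTAP19-5 (-0.15 ± 0.033, adjusted p = 0.298), KLF16 (0.14 ± 0.032, adjusted p = 0.304) and MIR142 (0.11 ± 0.028, adjusted p = 0.701), each in 9 of 9 biopsies and each at a low signal. Here too the count of biopsies lends no further support, as the genes were picked by p in these arrays. Camera called 7 lists at its preset correlation, with type I interferon-stimulated genes higher (median 0.22, 0 of 22 called over all genes and 0 adjusted over the list alone) and oxidative phosphorylation genes lower (-0.092, 0 of 34 by both). Adjusted p = 0.745 for both with an estimated correlation, and the exact permutation test called 0 lists. IRF7, an interferon regulatory factor, differed by 0.40 ± 0.18 and RSAD2, an antiviral enzyme, by 0.21 ± 0.13. Without biopsy 17 of the group after the drug, the mean of the type I interferon list differed by 0.061 against 0.24 with it, and RSAD2 by 0.048. Array weights and leaving out the arrays that stand apart each gave 1 call.

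Between biopsies on the drug and after it was stopped, limma again called 0 genes, with 637 at an unadjusted p under 0.05. NDUFA10 differed by 0.36 ± 0.11, KLRD1 by 0.37 ± 0.15 and SERPINA3 by -0.91 ± 0.46, none of which passed (adjusted p = 1 each; 9, 7 and 8 of 9 biopsies). DNASE1L2 (-0.14 ± 0.034), FAM89A (-0.44 ± 0.12) and FAM114A1 (-0.17 ± 0.043) had the smallest p-values. Camera called 13 lists at its preset correlation, with proximal tubule markers higher (median 0.52, 0 of 27 called over all genes and 0 adjusted over the list alone) and tubular injury and repair genes lower (-0.21, 0 of 31 by both). Adjusted p = 0.755 for both with an estimated correlation, and the exact permutation test called 0.

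At 10 days, biopsies without the drug (n = 15) were set against the 90-day controls, with 108 genes higher and 116 lower. SERPINA3 rose 4.84-fold (2.27 ± 0.37, adjusted p = 0.000143, 15 of 15 biopsies). RARRES1, a retinoid-responsive gene, rose 2.53-fold (1.34 ± 0.26, adjusted p = 0.00161, 14 of 15). S100A9, a calcium-binding protein of neutrophils and monocytes, rose 2.47-fold (1.30 ± 0.34, adjusted p = 0.0341, 14 of 15) and TGM2, a protein cross-linking enzyme, 2.12-fold (1.08 ± 0.24, adjusted p = 0.0101, 15 of 15). TNFRSF12A, the receptor of the cytokine TWEAK, rose 1.99-fold, CRYAB, a small heat shock protein, 1.94-fold and CFB, complement factor B, 1.88-fold, each in 15 of 15. Genes that fell included G6PC1, which completes gluconeogenesis (-1.27 ± 0.34, adjusted p = 0.04, 14 of 15), MYCN (-0.98 ± 0.20, adjusted p = 0.00434, 13 of 15) and PHGDH of serine synthesis (-0.75 ± 0.15, adjusted p = 0.00367, 13 of 15).

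Tubular injury and repair genes had 2 of 31 called over all genes, SERPINA3 and the secreted phosphoprotein SPP1 (0.83 ± 0.18), and 7 adjusted over the list alone. The list mean was 0.42 higher in 14 of 15 biopsies (permutation adjusted p = 0.0474; adjusted p = 0.246 with an estimated correlation). Complement genes had 2 of 23, CFB and C1R (0.67 ± 0.17), and 7 adjusted over the list alone, with a mean 0.29 higher in 13 of 15. Proliferation genes had 0 of 30 over all genes and 8 adjusted over the list alone, with a mean 0.21 higher in 12 of 15. Both had a permutation adjusted p of 0.0474, and adjusted p = 0.246 with an estimated correlation. The macrophage and matrix lists (14 of 25 and 11 of 32 adjusted over the list alone; 0 and 2 over all genes, the latter COL4A1 and COL15A1) had means 0.46 and 0.40 higher in 13 and 11 of 15 biopsies. Their permutation adjusted p-values were 0.056 and 0.0824, and adjusted p = 0.246 with an estimated correlation. Of the immediate early and stress genes 4 of 27 rose, among them ZFP36, which destabilises mRNAs (0.69 ± 0.15), DUSP1 and GADD45B, and 5 did when adjusted over the list alone. Their mean was 0.19 higher in 13 of 15 (permutation adjusted p = 0.0824), and adjusted p = 0.252 with an estimated correlation. Array weights gave 686 genes, leaving out the arrays that stand apart 470 and the proximal tubule covariate 352. A block on the biopsy number gave 80, against 241 on the same arrays without it.

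Biopsies at 10 days on the drug (n = 18) differed from the controls in 842 higher and 703 lower genes. SERPINA3 rose 3.67-fold (1.88 ± 0.36, adjusted p = 0.000841, 17 of 18 biopsies) and ANGPTL4, a secreted regulator of lipoprotein lipase, 2.82-fold (1.497 ± 0.339, adjusted p = 0.00407, 18 of 18). CD163, a scavenger receptor of macrophages, rose 2.57-fold (1.36 ± 0.28, adjusted p = 0.00178, 15 of 18). LCN2, a marker of tubular injury, rose 2.35-fold (1.23 ± 0.35, adjusted p = 0.0204, 17 of 18). SLC34A1, the main phosphate transporter of the proximal tubule, differed by -1.66 ± 0.44 (adjusted p = 0.0132, 16 of 18). FMO1 differed by -1.42 ± 0.40 (adjusted p = 0.0188, 14 of 18) and PLG, plasminogen, by -1.58 ± 0.43 (adjusted p = 0.015, 13 of 18).

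Of the tubular injury and repair genes 18 of 31 rose over all genes and 24 did adjusted over the list alone. The mean was 0.62 higher in 16 of 18 biopsies (permutation adjusted p = 0.00216; adjusted p = 0.197 with an estimated correlation). Macrophage and monocyte markers had 17 of 25 (23 adjusted over the list alone), with CD14 at 1.01 ± 0.21 and VSIG4 at 0.75 ± 0.16. Complement genes had 9 of 23 (12 higher and 1 lower adjusted over the list alone), with C1QC at 1.24 ± 0.27. Their means were 0.70 and 0.36 higher in 16 of 18 each (permutation adjusted p = 0.0132 and 0.0103; adjusted p = 0.217 for both with an estimated correlation). Matrix genes had 12 of 32 (14 adjusted over the list alone), led by the basement membrane collagen COL4A1 (1.09 ± 0.19, adjusted p = 0.000344, 17 of 18). Proliferation genes had 10 of 30 (19 adjusted over the list alone), including MCM4 (0.36 ± 0.083). Immediate early and stress genes had 8 of 27 (12 adjusted over the list alone), including JUN (0.65 ± 0.17). Their means were 0.41, 0.24 and 0.26 higher in 16, 15 and 16 of 18 biopsies (permutation adjusted p = 0.0229, 0.016 and 0.0167; adjusted p = 0.256 for each with an estimated correlation).

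Neutrophil markers in these biopsies had 4 of 18 higher, with S100A9 at 1.38 ± 0.33, and 1 lower, FCGR3B, a low-affinity antibody receptor (-0.17 ± 0.046). Adjusted over the list alone, 7 were higher and 1 lower. The mean was 0.31 higher in 14 of 18 (permutation adjusted p = 0.0359; adjusted p = 0.408 with an estimated correlation). Proximal tubule markers were lower, with 7 of 27 called over all genes and 20 adjusted over the list alone. Among them were ALPL (-1.101 ± 0.258), G6PC1 (-1.33 ± 0.33) and HAO2 (-1.30 ± 0.33). Their mean differed by -0.80 in 13 of 18 biopsies and missed the permutation threshold (adjusted p = 0.0632; adjusted p = 0.269 with an estimated correlation). IFNG-inducible genes, which had 14 calls on the drug at 90 days, had 0 of 19 here over all genes and 0 adjusted over the list alone. They had a mean 0.29 higher in 14 of 18 biopsies (permutation adjusted p = 0.187; adjusted p = 0.589 with an estimated correlation). CXCL9 differed by -0.022 ± 0.47. The count was 592 with the arrays of the 2 groups alone and 196 with the proximal tubule covariate. A block on the biopsy number gave 4, against 367 on the same arrays without it.

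The 10-day groups shared 75 higher and 84 lower calls against the same controls. Independent lists of those sizes would share 4.56 and 4.09. Simulated groups without a change, with the arrays' deviations from their group means dealt out at random, shared at most 0. With no change few genes are called at all, so this cannot show what the shared controls add. With the controls split between the comparisons, 7 and 156 higher genes were called with 4 shared, and 3 and 165 lower genes with 1 shared.

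Set against each other directly, 10-day biopsies on the drug and without it differed in 1 called gene, with 2406 at an unadjusted p under 0.05. CRY1, a repressor of the circadian clock, was higher on the drug by 0.47 ± 0.093 (adjusted p = 0.05, 17 of 18 biopsies). Proximal tubule markers (median -0.49, 0 of 27 called over all genes and 0 adjusted over the list alone) and type I interferon-stimulated genes (-0.19, 0 of 22 by both) were among 8 lists called by camera at its preset correlation. HAO2 differed by -0.90 ± 0.32, PCK1 of gluconeogenesis by -0.83 ± 0.30 and IFIT1 by -0.40 ± 0.16, none past the threshold. B cell markers had 0 of 15 called over all genes and 3 higher adjusted over the list alone, including FCRLA (0.40 ± 0.096, 18 of 18 biopsies). Their mean was 0.089 higher in 18 of 18 (permutation adjusted p = 0.0869). Adjusted p = 0.86 for these 3 lists with an estimated correlation, and the permutation test called 0 lists. The CRY1 call was lost in the fit of these arrays alone, with every probe by itself, with the biopsy number as a block (and on the same arrays without the block) and with the proximal tubule covariate.

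Without the drug, 10-day biopsies (n = 15) were compared with 90-day biopsies (n = 14) for the change with time. CRYAB was 2.28-fold higher at 10 days (1.19 ± 0.18, adjusted p = 0.000121, 15 of 15 biopsies) and TMEM252 2.07-fold (1.05 ± 0.23, adjusted p = 0.043). S100A1 was 2.01-fold (1.01 ± 0.20, adjusted p = 0.016) and C8G, a chain of complement component C8, 1.42-fold (0.51 ± 0.11, adjusted p = 0.043). KLRB1 differed by -1.12 ± 0.23 (adjusted p = 0.016), and CD247 by -1.02 ± 0.20 (adjusted p = 0.016). IL2RB, a chain of the interleukin 2 receptor, differed by -0.76 ± 0.17 (adjusted p = 0.043) and CRY1 by -0.49 ± 0.099 (adjusted p = 0.016), each in 15 of 15. NK and cytotoxic genes had 1 of 26 lower over all genes and 15 adjusted over the list alone, and a mean difference of -0.37 in 15 of 15 (permutation adjusted p = 0.00768). T cell markers had 1 of 21 and 11 adjusted over the list alone, with a mean difference of -0.27 in 14 of 15 (permutation adjusted p = 0.022). Both calls held with an estimated correlation (adjusted p = 0.0174 and 0.0454). Neutrophil markers went the other way, with a mean of 6.91 against 6.70 in 13 of 15 biopsies. Macrophage markers differed little (8.10 against 8.07). The permutation test called neither of these lists. The 8 genes called became 52 with array weights, 39 without the arrays that stand apart and 54 with the proximal tubule covariate, each including all 8. It was 16 with cyclic loess, 25 with only genes above the middle of mean level, 5 with the arrays of the 2 groups alone or every probe by itself, and 8 with the biopsy number as a block, which kept 3 of these 8.

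**Figure D4:**
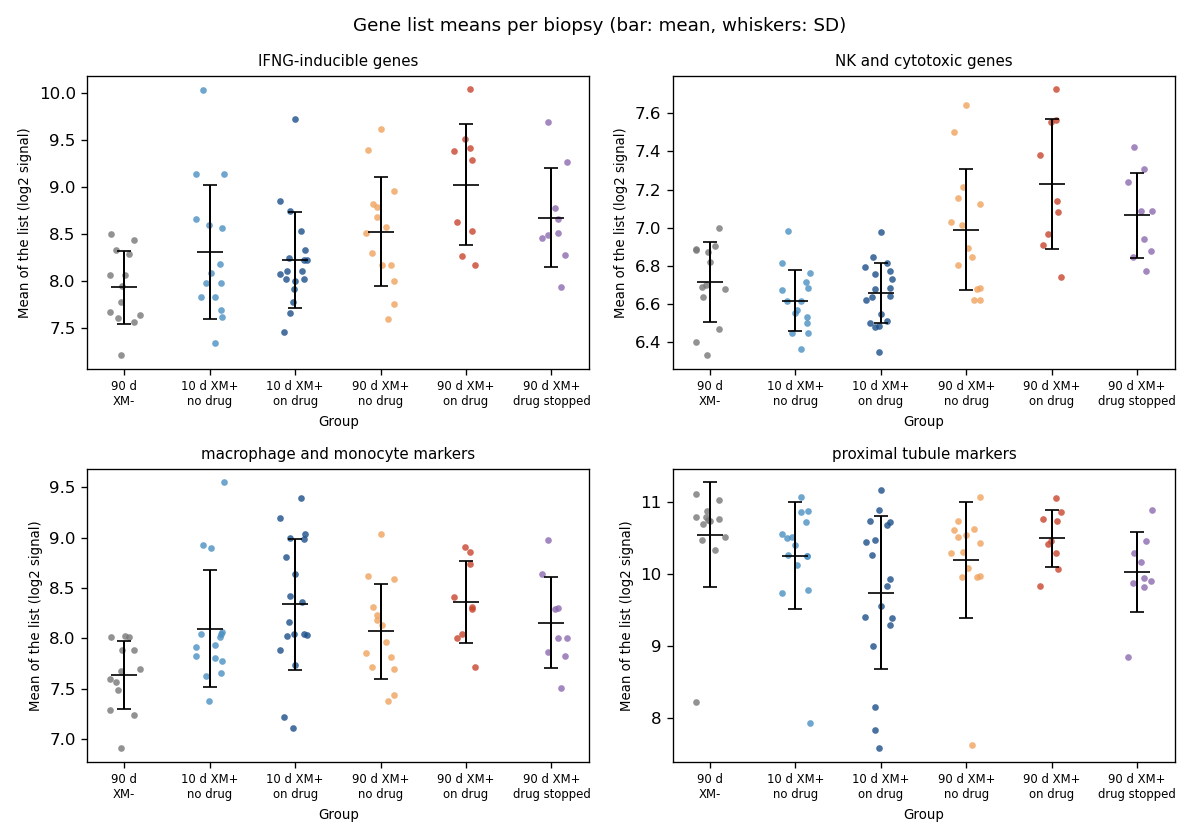
Mean log2 signal of 4 gene lists in each biopsy (points) of the 6 groups, with the group mean (bar) and SD (whiskers). The NK and cytotoxic mean is 6.62 and 6.66 in the 10-day groups and 7.23 in 90-day biopsies on the drug. The macrophage mean is 8.34 and 8.36 in the groups on the drug, and the proximal tubule mean spreads most in 10-day biopsies on the drug (SD 1.06).

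On the drug, 10-day biopsies (n = 18) had 67 lower and 15 higher genes than 90-day biopsies (n = 9). CXCL9 was 5.79-fold lower at 10 days (-2.53 ± 0.53, adjusted p = 0.0065, 17 of 18) and KLRB1 3.06-fold (-1.61 ± 0.25, adjusted p = 6.57e-05). CCL5, a chemokine of T and NK cells, was 2.92-fold lower (-1.54 ± 0.29, adjusted p = 0.00226) and CD247 2.73-fold (-1.45 ± 0.22, adjusted p = 6.57e-05), each of the last 3 in 18 of 18. ANGPTL4 was 3.23-fold higher (1.69 ± 0.38, adjusted p = 0.0157, 18 of 18) and TNFRSF12A 1.99-fold (0.997 ± 0.229, adjusted p = 0.0188, 16 of 18).

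NK and cytotoxic genes had 16 of 26 lower over all genes and 19 adjusted over the list alone, including GZMA (-1.43 ± 0.24) and GNLY (-1.41 ± 0.23). T cell markers had 8 of 21 and 13 adjusted over the list alone, including CD3D (-1.31 ± 0.25) and CD6 (-0.71 ± 0.14). Their means differed by -0.57 and -0.39 in 18 of 18 biopsies (exact permutation adjusted p = 0.000133 and 0.000719), and both calls held with an estimated correlation (adjusted p = 0.000684 and 0.0138). IFNG-inducible genes had 4 of 19 lower over all genes and 12 adjusted over the list alone. They had a mean difference of -0.80 in 17 of 18 (exact permutation adjusted p = 0.0136; adjusted p = 0.0976 with an estimated correlation). Macrophage markers had 0 of 25 called over all genes and 0 adjusted over the list alone. They had a mean difference of -0.024 (exact permutation adjusted p = 0.964, 10 of 18 biopsies). The count was 145 with array weights, 43 with the arrays of the 2 groups alone and 52 without the arrays that stand apart. With the biopsy number as a block it was 0, against 35 on the same arrays without it.

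The drug's difference at 10 days was last set against that at 90 days, and limma called 0 genes, with 1158 at an unadjusted p under 0.05. CXCL9 differed by -1.66 ± 0.71 between the days, UBD by -1.22 ± 0.47 and HAO2 by -1.29 ± 0.50, none of which passed (adjusted p = 0.827 each). HCG4B (-0.16 ± 0.040), KIF7 (0.20 ± 0.051) and SLC17A8 (0.15 ± 0.040) had the smallest p-values. Camera called 9 lists at its preset correlation, among them proximal tubule markers (median -0.86, 0 of 27 over all genes and 0 adjusted over the list alone) and IFNG-inducible genes (-0.52, 0 of 19 by both), and adjusted p = 0.761 for both with an estimated correlation.

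Podocyte markers had list means within 0.095 of each other (log2) between the groups compared, with 1 of 18 members called at most. Camera at its preset correlation called them lower in 90-day biopsies on the drug (mean 7.54), against controls (7.63) and against biopsies without the drug (7.63). Neither call held with an estimated correlation or in the permutation test. In 10-day biopsies on the drug against controls, markers of the loop, distal tubule and collecting duct had 0 of 26 called (median -0.089), hypoxia-responsive genes 2 higher and 1 lower of 19 (median 0.028), cytosolic ribosomal protein genes 1 lower of 36 (-0.009) and plasma cell markers 0 of 13 (-0.03). Their permutation adjusted p-values were 0.4, 0.8, 0.571 and 0.677, with the direction of the mean in 10, 9, 11 and 11 of 18 biopsies. Glucocorticoid-responsive and metallothionein genes had 2 of 21 higher at 10 than at 90 days on the drug, one of them CEBPD, a transcription factor (0.59 ± 0.14). They had a mean 0.40 higher in 13 of 18 biopsies (exact permutation adjusted p = 0.11). Of the 288 list results, 22 had a median, mean and test that differed in sign, all without a call and with medians of at most 0.034 in size.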

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

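The rules for picking these values were fixed before the data were seen, but the differences without a biopsy were chosen only after the result was seen. In the groups of 9 biopsies, the gap between the most extreme biopsy and its nearest neighbour was divided by the range of the group. Of 103 values checked, for named genes and list means, 9 had a ratio above Dixon's 95% critical value, and chance flags about 1 in 20. Of these 9, 3 lay in biopsy 17 of the 90-day group after the drug was stopped, where interferon genes were high. The ratio was 0.647 for the mean of type I interferon-stimulated genes (9.97 against 7.94 to 8.66 in the others), 0.748 for RSAD2 and 0.502 for ISG15. Without this biopsy, the difference of the list mean went from 0.474 to 0.291 against controls and from 0.245 to 0.061 against biopsies without the drug. Biopsy 6 of the 90-day group on the drug was high in injury genes, with 0.594 for the mean of the tubular injury list (9.95 against 8.77 to 9.25) and 0.577 for SERPINA3. CEBPD, of the glucocorticoid-responsive list, was highest in this biopsy as well (0.576). Without biopsy 6, the injury list was 0.479 higher at 10 than at 90 days on the drug (exact permutation adjusted p = 0.0391), against 0.379 with it (0.11). At 90 days on the drug against controls, the list was 0.146 higher without this biopsy (exact permutation adjusted p = 0.291), against 0.246 with it (0.134). The other 3 were C3AR1, lowest in biopsy 9 on the drug (0.499), the oxidative phosphorylation mean, highest in biopsy 5 on the drug (0.5), and the mean of loop, distal tubule and collecting duct markers, highest in biopsy 18 after the drug was stopped (0.508).

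The drug's difference at 10 days was set against that at 90 days for each list, and 9 lists were called at camera's preset correlation. The median member differed between the days by -0.865 for proximal tubule markers, -0.516 for IFNG-inducible genes, -0.302 for class I antigen presentation, -0.251 for type I interferon-stimulated genes and -0.178 for NK and cytotoxic genes. It differed by -0.097 for plasma cell markers, -0.064 for T cell markers, -0.076 for oxidative phosphorylation genes and 0.22 for tubular injury and repair genes. With an estimated correlation 0 lists were called, with adjusted p-values from 0.761 to 0.849 for these 9.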

How the results depend on the processing

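In the settings with 1 probe per gene, no called gene named here and no called list turned its direction. The proximal tubule covariate was not run for lists. Of the gene results named here, cyclic loess kept 125 on their side of the threshold and ended 6 calls. Array weights kept 123 and gained 8, and leaving out the 7 arrays that stand apart kept 125, gained 4 and ended 2. Only genes above the middle of mean level kept 111, gained 1 and ended 0, as lower genes were not in that fit. The arrays of the compared groups alone kept 109, gained 1 and ended 21. The proximal tubule covariate kept 108 and ended 23, and the biopsy number as a block kept 43 and ended 82. Signals near the background limit the differences of weakly expressed genes. Except where the setting's own construction shows it (fewer arrays, fewer or more tests, a larger assumed correlation), the cause was not tested.

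Genes called, with the values above first, were as follows. For 90-day biopsies without the drug against controls (13), cyclic loess gave 8, array weights 763, leaving out the arrays that stand apart 136 and every probe by itself 7. On the drug against controls (181), the arrays of the groups compared gave 328, array weights 668, leaving out the arrays apart 485 and the covariate 302. After the drug was stopped against controls (77), only genes above the middle of mean level gave 200, the arrays of the groups compared 741, array weights 1849, leaving out the arrays apart 1584 and the covariate 41. After the drug was stopped against without it (0), array weights and leaving out the arrays apart gave 1 each. At 10 days without the drug against controls (224), array weights gave 686, leaving out the arrays apart 470 and the covariate 352. At 10 days on the drug against controls (1545), the arrays of the groups compared gave 592 and the covariate 196. Between the 10-day groups (1), the arrays compared, every probe by itself and the covariate gave 0, and leaving out the arrays apart 2. Between the days without the drug (8), cyclic loess gave 16, genes above the middle level 25, the arrays compared 5, array weights 52, leaving out the arrays apart 39, the covariate 54 and every probe by itself 5. Between the days on the drug (82), the arrays compared gave 43, array weights 145 and leaving out the arrays apart 52. The fit without these arrays, the covariate and the permutation test were chosen after seeing the data.

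Gene lists called at the preset correlation numbered 16, 17 and 15 in the 90-day groups against controls (without the drug, on it, after it), 14, 7 and 13 between these groups (on against without, after against without, on against after), 16 and 13 in the 10-day groups against controls (without, on), 8 between the 10-day groups, 12 and 16 between the days (without, on) and 9 for the drug's difference between days. With an estimated correlation these became 0, 8 and 0, then 0, 0 and 0, then 0 and 0, then 0, then 2 and 2, then 0. The permutation test gave 7, 9 and 11, then 0, 0 and 0, then 3 and 7, then 0, then 2 and 3, and was not run on the difference between days. After the drug was stopped against without it, lists fell from 7 to 4 with genes above the middle level and to 4 without the arrays apart.

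With the biopsy number as a block, genes called were 1 (without the drug), 0 (on it) and 0 (after it) at 90 days against controls, 80 (without) and 4 (on) at 10 days against controls, 0 between the 10-day groups and 0 between the days on the drug. After the drug was stopped against without it, 19 lists were called, as on the same 10 arrays without the block. Between the days without the drug the block gave 8 genes, of which 3 were among the 8 of the fit without it. The block numbers did not clearly pair biopsies by expression. Between the days without the drug, the correlation within a number ran from -0.26 to 0.46. There 0 of 14 biopsies were most alike to the one of their own number. In the other pairs of groups checked, at most 1 biopsy was. The highest median correlation, 0.24, came from only 5 pairs, after the drug was stopped and without it at 90 days. For 90-day biopsies on the drug against after it was stopped, no paired analysis was possible because these groups share no numbers. Against the controls a shared number cannot mark the same transplant, since the crossmatch differs. Calls lost with the block there cannot be read as an effect of pairing.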

Other observations

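The tests of more medulla, of arrays apart for the proximal tubule and of fewer leukocytes were chosen only after the result was seen. The other tests were written down before their own values were seen, those of the small shifts, of the arrays apart for NK genes and of the clock once the pattern itself was known. The 13 genes called at 90 days without the drug shifted the same way against the controls in all 5 positive crossmatch groups. The mean shift, signed by its direction, was 0.318 and 0.317 in the 10-day groups without and on the drug, and 0.335, 0.312 and 0.374 in the 90-day groups without, on and after it. In each group 13 of 13 had the same sign, and 10, 13, 13, 10 and 12 were called. The genes were picked in the 90-day group without the drug, so its own signs and calls were fixed by that choice. In 20 simulations of unchanged groups, the 13 genes with the smallest p, called or not, kept a median of 13 signs (lowest 9). Their median shift was 0.157 at picking, and the shift kept had a median of 0.073 and was at most 0.238. The real genes shifted by 0.335 at picking, so the sizes kept cannot be compared directly.

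The proximal tubule mean at 10 days on the drug differed from that in controls by -0.802 (unadjusted 95% interval -1.43 to -0.17), but missed the threshold over the 24 lists (permutation adjusted p = 0.0632; adjusted p = 0.269 with an estimated correlation). If these cores held more medulla, principal cell genes should be higher, by 0.0963 from their slope on the proximal tubule mean; they differed by -0.067 (-0.327 to 0.193, permutation p = 0.623), which leaves this open. Without the arrays that stand apart, 4 of 18 in this group, the difference was -0.568 (-0.94 to -0.196), so these arrays may carry part of it. At 10 days without the drug the proximal tubule mean differed by -0.288 from controls and by 0.061 from 90-day biopsies without the drug. A biological loss of tubular transcripts at 10 days on the drug could not be told from more medulla or from the arrays that stand apart. No 10-day controls were analysed here, so between these biopsies and the controls the day, the crossmatch and the drug change together.

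The NK and T cell genes were lower at 10 than at 90 days on the drug. If leukocytes of every kind were fewer at 10 days, macrophage markers should fall alike, but the NK mean minus the macrophage mean on each array differed by -0.549 (-0.828 to -0.269, permutation p = 0.0109), and macrophage markers by -0.0241. Without the drug this difference was -0.399 (permutation p = 0.00626). Leaving out the arrays that stand apart gave -0.559 against -0.573 for the NK mean, so they do not account for it. A change in NK and T cells with time or treatment after transplantation remains possible, and the design does not separate these.

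Small shifts of the same genes between the controls and every other group could come from the crossmatch itself, from the probes or from chance values of the shared controls. Other probes of the genes tested gave a median ratio of 0.626 (0.18 to 0.72, 23 probes of 19 genes) to the first probe's difference. Reference genes, called between the days on the drug, gave 0.837 (0.4035 to 1.007, 9 probes of 7 genes). A probe-specific shift is left open. That test was planned for the called genes, which have only 2 other usable probes. It therefore ran on 79 genes with an unadjusted p under 0.01 and the same direction in all 5 comparisons. Picking on the same arrays also lowers the ratio. The 79 include genes such as RARRES1 and TGM2, which changed by more than 1.5-fold at 10 days without the drug against controls. The ratio therefore does not speak for the small shifts alone. For a test of chance, 7 controls were used for picking and the other 6 for measuring. The 13 genes picked this way need not be the 13 called genes. Their shift at picking was 0.558, in biopsies without the drug at the later day. In 10-day biopsies on the drug, over the other 6 controls, it was 0.418 (0.242 to 0.595), and 12 kept their sign. The interval reaches under 0.279, so chance values of the controls may account for part. The day and the drug also change between these values, and the genes were selected on the first. The drop therefore cannot be assigned to the controls. A batch of arrays could not be tested, as no dates or array positions were used here. The crossmatch separates the controls from every other group, so an effect of it could not be told apart from these.

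CRY1 was the only gene called between the 10-day groups. It was also called lower at 10 than at 90 days without the drug, by a like amount. Both calls share the 10-day group without the drug, so the difference is not shown to be a rise with the drug. Of 15 other clock genes 5 had an unadjusted p under 0.05, NR1D2 (-0.321), CIART (-0.414), TEF (-0.267), DBP (-0.238) and BMAL1 (0.208). At the share of all genes with such a p 1.81 would be expected, and 2.14 at that of genes of like mean level. The excess over this was not tested, so a shift of the circadian clock stays open, and the hour of biopsy is not used here.

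The arrays of each comparison were also split at random, with the real grouping counted among the 100 splits. As many genes as in the real grouping were called in 1 split for 90-day biopsies without the drug against controls (real 13, highest other 1), 1 on the drug (181, 0, though 1 simulation called 698 unchanged genes in this comparison), 1 after it was stopped (77, 1), 1 at 10 days without the drug (224, 1) and 1 at 10 days on it (1545, 55). Between 90-day groups all 100 splits reached the real 0, with highest others of 13 (on against without), 1 (after against without) and 1 (on against after). Between the 10-day groups 12 splits reached the real 1, with a highest of 660; between the days 2 reached 8 without the drug (highest 57) and 3 reached 82 on it (highest 631), and for the drug's difference between days all 100 reached 0 (highest 3). Splits that call several times the real count point to a structure of the samples. Those with 660, 57 and 631 genes differed in the proximal tubule mean by 0.802, 0.655 and 1.031, where the largest in any random split was 0.916, 0.658 and 1.031. The split with 13 genes differed by 0.346, against 0.655 in another split with no more calls, so the proximal tubule mean alone does not set the count.

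For gene lists at the preset correlation, 7 splits reached the real 16 at 90 days without the drug against controls (highest other 18), 2 the 17 on it (17), 17 the 15 after it (20), 8 the 16 at 10 days without it (18) and 13 the 13 at 10 days on it (18). Between 90-day groups the numbers were 19 for 14 on against without (18), 72 for 7 after against without (19) and 22 for 13 on against after (20). They were 59 for 8 between the 10-day groups (18), 39 for 12 between the days without the drug (17), 8 for 16 on it (19) and 61 for 9 in the drug's difference between days (18). List calls at the preset correlation are therefore common in random splits of these arrays.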
